A study of Caenorhabditis elegans with 2 samples.

How the data were processed

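The samples were 2 biological replicates of whole L1 larvae of strain YL398, which form 1 group. The group and the replicate numbers come from the sample labels, which also give a fragment size range of 150 to 350 bp. The authors deposited, per the labels and the notes with the files, 4 kinds of peak list in the ce10 and ce11 builds: a relaxed list for each replicate, a relaxed list of both replicates pooled, and a list thresholded by the irreproducible discovery rate (IDR), derived from the other 3. Per those notes, each list was called against a control alignment, which was not used here. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here.

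The deposited peak lists give a signal value per peak, the enrichment as the authors' caller scored it, which is not comparable in size between lists. It was used to describe, rank and filter peaks within a list. They also give the −log10 q-value per peak, as deposited by the authors, which was described only, and the offset of the summit from the peak start. The read depth is unknown. The ce11 IDR list, called the reproducible set, was the main peak set, and it equals the 6712 peaks of the pooled list with the highest signal. The −log10 q-value in that list ran from 3.53 to 4.01. The set holds 12 peaks that share coordinates with another peak, and 3 summits lie past the peak end; all were kept. The maximum width was 3808 bp. All samples, lists and columns described in the labels were assigned, and no column of unknown origin was used.

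Gene models came from Ensembl release 115 on WBcel235, the assembly that ce11 also names, and sequence from the matching RefSeq genome. The chromosome names and lengths fit the ce11 coordinates, and ce10 coordinates were used only to count and overlap peaks within ce10. A promoter window ran from 500 bp upstream to 200 bp downstream of each annotated transcript start. Summits outside these windows were placed in coding exons, UTR exons, introns or intergenic sequence, in this order. The background peaks were the 22738 pooled relaxed peaks that overlap no reproducible peak.

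The following choices were made before the data were examined: the tests, the 17 gene lists, the motifs and the genes to be named. Named genes are the transgene parts ges-1, lin-35 and unc-119; the genes nearest the 15 strongest peaks; from each list past the threshold, the 3 members with the strongest promoter peak and the first 2 by name without one; from every other list, the strongest member; and the peak with the largest rank difference between replicates. 6 lists, from ribosomal proteins to chemoreceptors, took every gene whose symbol has the family's form; in the others every symbol but rad-54 matched the annotation. Some loci share a symbol in the annotation, so the 72 histone genes carry 50 symbols and the 1290 chemoreceptor genes 1280, and each locus counted once. Gene lists and non-coding classes were tested with Fisher's exact test, two-sided, against all other genes, with Benjamini-Hochberg adjustment and a threshold of 0.05. Replicate signal was correlated over peaks with a permutation test of 100000 resamples. Motifs were searched on both strands within 75 bp of the summit and around the position 500 bp at lower coordinate, and compared with an exact McNemar test; each consensus was also searched reversed without complementing. IUPAC codes S and Y stand for C or G and C or T. Chromosome comparisons used Fisher's exact test per gene. Intervals are 95% Wilson intervals. They and the p-values take peaks or genes as units, so they measure neither biological variation between larval cultures nor mapping errors.

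The alternatives were other promoter windows, the ce10 lists, stricter overlaps, the 3356 strongest peaks, assignment to the nearest start within 2 kb, narrower backgrounds, other motif windows and flanks, and each replicate alone, taken as its 6712 strongest peaks. A set of the 4695 reproducible peaks that overlap the strongest lists of both replicates was added after seeing the data.

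The following steps were tested on simulated data. Promoter assignment recovered 100% of 2000 planted genes. With simulated lists of 30 genes, 100% of 200 lists with an odds ratio of 20 and 77.5% of those with an odds ratio of 4 were called, and 0.433% of 3000 lists with no difference. E2F, CHR and GATA sites planted in random windows were all found, and overlaps equalled those of bedtools 2.31.1. With 6000 windows the exact McNemar test called 97% of 200 simulated differences of 3 percentage points and 4% of those with none, unadjusted. The permutation test of a correlation called 99% of 200 simulated relations and 4% of those with none. A planted word ranked 1 among the 6-base words, and a planted spacing of 5 bp was the most frequent. The chromosome comparisons and the permutation test of signal by list were not simulated. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.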

Results

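LIN-35 is the worm member of the retinoblastoma family of pocket proteins and a subunit of the DREAM complex, which represses cell cycle genes together with E2F and DP proteins. Chromatin immunoprecipitation with sequencing mapped its binding sites in whole first-stage (L1) larvae of Caenorhabditis elegans, both sexes together. The strain, YL398, carries a transgene in which the promoter of ges-1, a gut esterase gene, drives LIN-35 fused to GFP and FLAG. The fusion is followed by the lin-35 3'UTR, and a wild-type unc-119 copy serves as the transgene marker. The labels name LIN-35 as the antibody target in one field and the GFP fusion in another, so whether LIN-35 made from the endogenous gene was also precipitated is open. If only the fusion was precipitated, the peaks may come mainly from gut cells. A lack of peaks at genes of other tissues would then not describe LIN-35 in those tissues. There was 1 group with 2 biological replicates, and no comparison with another genotype, stage or factor was analysed here. The data are lists of peaks, each with a position, a summit and a signal value given by the authors. The read depth is unknown from these lists, so the precision of a single peak cannot be given. The 95% Wilson intervals below are over peaks or genes and cover counting error only. Positions are in the ce11 build.

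The reproducible set held 6712 peaks with a median width of 344 bp and covered 1.98% of the genome. Their signal ran from 45.9 to 4903, with a median of 98.5. The 15 strongest peaks all had their summit in the promoter window of a protein-coding gene, from 500 bp upstream to 200 bp downstream of an annotated transcript start. The strongest lay at cdc-48.1, which encodes a p97 ATPase (chromosome II, 10563368 to 10563794, summit 171 bp upstream of the start, signal 4903). It was followed by rpl-3, a ribosomal protein gene (chromosome III, 3867342 to 3867766, 291 bp upstream, signal 4900), and by sec-61.G, which encodes a subunit of the translocon (chromosome V, 10897194 to 10897601, 237 bp upstream, signal 4424). The next 12 were nearest to citk-2, rpl-35, Y53F4B.11, eelo-2, the alpha-tubulin gene tba-2, tasp-1, dld-1, the E2F gene efl-1, fbxl-2, cox-5A, fipr-17 and F48A11.4, with signals from 3801 down to 2633. In a window of 250 bp either side of the start, rpl-3, rpl-35, dld-1, cox-5A and fipr-17 had no promoter peak. These 15 peaks ranked 1 to 15 in replicate 1 and 1 to 55 in replicate 2 among the reproducible peaks.

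Which sites both replicates found was asked first. Of the 6712 reproducible peaks, 6700 (99.8%, interval 99.7 to 99.9) overlapped a peak of replicate 1 by at least 1 bp, and 6183 (92.1%, 91.4 to 92.7) a peak of replicate 2. These replicate lists hold 30000 and 26341 peaks and include background. Against only the 6712 strongest peaks of each replicate, the shares were 96.5% (96.0 to 96.9) for replicate 1 and 73.0% (72.0 to 74.1) for replicate 2, and 4695 peaks (69.9%) overlapped both. Signal in the replicates rose together across the 6172 peaks with a partner in both lists, with Spearman's rho 0.652 and Pearson's r 0.747 on the log scale (2 relations, two-sided permutation p = 1e-05 for each, the smallest that 100000 resamples can give). This is a correlation across peaks within 1 pair of libraries, and peaks are not independent replicates. The peaks were also selected through both replicates, so the p is no independent test of their agreement. The signal of the reproducible set followed replicate 1 (rho 0.975) more closely than replicate 2 (rho 0.694). Some strong peaks had no partner in the list of replicate 2, among them the promoter peak of rde-4, a double-stranded RNA binding protein gene of the RNA interference pathway (chromosome III, 10218603 to 10218898, signal 674, rank 422). The largest difference in rank among peaks found in both replicates was at F59A1.11, where an intronic summit on chromosome V at 17662464 ranked 6699 by replicate 1 and 1196 by replicate 2 signal among the reproducible peaks. A requirement of 50% reciprocal overlap lowered the share found among the strongest peaks of replicate 2 to 61.9%.

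**Figure D1:**
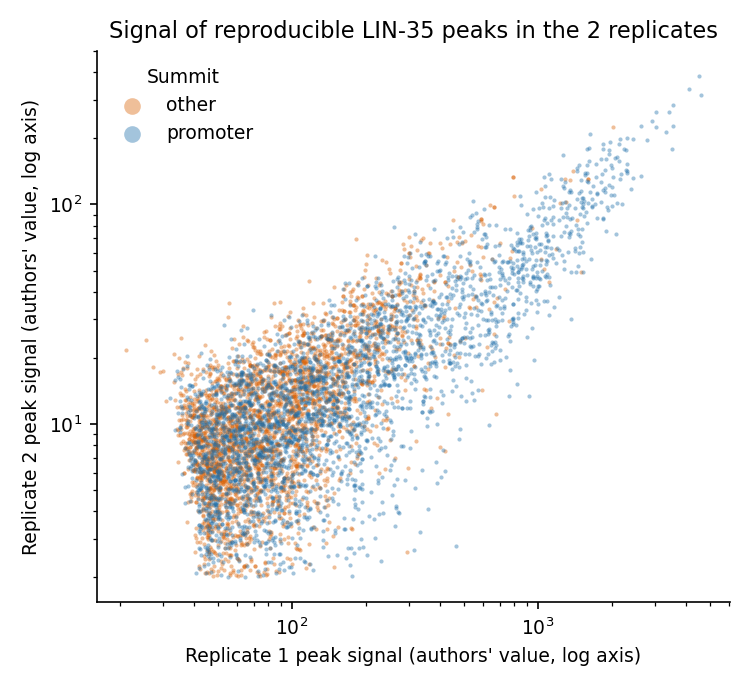
Signal of each reproducible peak found in both replicates, replicate 1 on the horizontal and replicate 2 on the vertical log axis, with 1 point per peak (6172 peaks) coloured by whether the summit lay in a promoter window. The points rise together (Spearman's rho 0.652), and most peaks above a signal of 1000 in replicate 1 are at promoters.

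Reproducible peaks were concentrated at promoters of protein-coding genes. Of the 6712 summits, 3394 (50.6%, interval 49.4 to 51.8) lay in a promoter window, against 4921 of 22738 (21.6%, 21.1 to 22.2) for peaks of the pooled relaxed list that overlapped no reproducible peak (Fisher's exact test, two-sided, with a p below the smallest number the software represents). Among the 3356 strongest peaks the promoter share was 59.5% (57.8 to 61.2), and with the starts of genes of any biotype it was 62.9% (4221 of 6712). The share depended on the window. With 1000 bp upstream to 200 bp downstream it was 60.8%, against 31.7% of the background peaks. With 250 bp either side it was 38.1% against 17.5%. Summits in coding exons were 1.42% of the reproducible and 23.9% of the background peaks. Among the 6712 strongest peaks of each replicate they were 1.49% for replicate 1 and 5.14% for replicate 2. Introns held 16.7% of the reproducible summits, UTR exons 1.58%, and 29.8% lay between genes. Because a summit can lie in the windows of several genes, these summits gave a promoter peak to 3959 of the 19973 protein-coding genes (19.8%).

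Promoters of DNA replication, mitosis and DNA repair genes were bound far more often than those of other genes. In the DNA replication list 35 of 40 genes (87.5%, interval 73.9 to 94.5) bore a promoter peak, with an odds ratio of 28.6 against all other protein-coding genes (adjusted p = 2.87e-19, Fisher's exact test with Benjamini-Hochberg adjustment over 17 lists). The strongest were orc-5, which encodes a subunit of the origin recognition complex (signal 1805), the clamp loader gene rfc-4 (1657) and ctf-4 (1615). Of the 5 without a peak, orc-2 and pole-2 come first by name. The cell cycle and mitosis list had 40 of 59 genes (67.8%, 55.1 to 78.3; odds ratio 8.59, adjusted Fisher p = 6.84e-15), led by the cyclin B gene cyb-1 (1805), the securin gene ify-1 (1425) and the kinetochore gene knl-3 (1230). The genes cdc-25.1 and cdc-25.2, which encode phosphatases that activate cyclin-dependent kinases, had none. A peak on chromosome IV, 10734541 to 10734897, served both orc-5 and cyb-1, 131 and 497 bp upstream of their starts, and the ify-1 peak was also that of the ribosomal protein gene rpl-22. With assignment to the nearest start ctf-4, cyb-1 and knl-3 lost their peaks, the last 2 also in a window of 250 bp either side. In the DNA repair list 18 of 25 genes (72.0%, 52.4 to 85.7; odds ratio 10.4, adjusted Fisher p = 5.94e-08) bore a promoter peak, with the polymerase gene polh-1 (2291), mrt-2 (1404) and exo-1 (1393) the strongest, and brc-2 and clk-2 without one. The polh-1 peak also served the ribosomal protein gene rps-22. The 3 lists passed under every alternative, but their odds ratios depended on it. Against genes with a relaxed pooled peak at the promoter they were 11 for DNA replication, 3.41 for cell cycle and mitosis and 3.36 for DNA repair, with assignment to the nearest start 11.9, 4.09 and 5.16, and with replicate 2 alone 16.1, 7.32 and 4.29.

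Genes for the DREAM complex itself and other synMuv B factors, which act with LIN-35 in repression, were bound in 9 of 17 cases (52.9%, interval 31.0 to 73.8; odds ratio 4.56, adjusted Fisher p = 0.00455). The E2F gene efl-1 had the strongest of these peaks (chromosome V, 16965626 to 16966029, signal 3137), followed by the DNA-binding subunit gene lin-54 (1610) and lin-9 (1246). The lin-54 peak was also that of the ribosomal protein gene rpl-12, and lin-54 lost it with assignment to the nearest start and in the window of 250 bp either side. The genes hpl-2 and lin-13 had none, but lin-13 gained one in a window of 1000 bp upstream to 200 bp downstream, where the list had 12 of 17 genes (odds ratio 7.57), and with assignment to the nearest start. Against only those genes with a relaxed pooled peak at their promoter, of which 51.8% outside the list bore a reproducible one, this list no longer passed (9 of 15, adjusted Fisher p = 0.651), nor did it in the narrower window (5 of 17, adjusted p = 0.150).

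Lists of broadly expressed genes were also bound more often than other genes. Ribosomal protein genes bore a promoter peak in 67 of 76 cases (88.2%, interval 79.0 to 93.6; odds ratio 30.6, adjusted Fisher p = 9.11e-37), proteasome genes in 27 of 33 (81.8%, 65.6 to 91.4; odds ratio 18.3, adjusted p = 1.04e-13) and nuclear pore genes in 22 of 26 (84.6%, 66.5 to 93.9; odds ratio 22.4, adjusted p = 6.03e-12). Besides rpl-3, the strongest ribosomal protein peaks were at rpl-35 (3748) and rps-12 (2439), and rpl-16 and rpl-25.1 had none. The strongest proteasome peaks were at rpn-11 (1330), rpn-5 (1059) and rpt-1 (1035), with none at pas-1 and pbs-5. The strongest nuclear pore peaks were at npp-3 (2561), npp-19 (1987) and npp-22 (1164), with none at npp-12 and npp-21. In the window of 1000 bp upstream pas-1, npp-12 and npp-21 gained one, and rps-12 lost its peak with assignment to the nearest start. Summits at ribosomal protein genes lay farther upstream of the nearest annotated start than those at replication genes. The median was 288 bp (interquartile range 252.5 to 358.5, 67 genes) against 143 bp (123.5 to 173.5, 35 genes). Where transcription begins was not measured, so this gap may lie in the annotated starts. With the window of 250 bp either side, only 14 of 76 ribosomal protein genes bore a peak and the list did not pass (odds ratio 1.36, adjusted Fisher p = 0.390). With assignment to the nearest start the odds ratios fell to 4.50 for ribosomal protein, 6.03 for proteasome and 6.50 for nuclear pore genes, and with replicate 2 alone to 10.7 for proteasome and 8.79 for nuclear pore genes, all still past the threshold. Over all alternatives the odds ratio ran from 1.36 to 46.6 for ribosomal protein, 6.03 to 31.7 for proteasome and 6.50 to 42.1 for nuclear pore genes. The shares did not differ detectably from the 87.5% of the replication list in the main window (Fisher p = 1, 0.530 and 0.730), but with assignment to the nearest start 56.6% of the ribosomal protein genes were bound against 77.5% of the replication genes (Fisher p = 0.0276).

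Among the tissue lists only that of gut genes was bound more often than other genes, and this call depended on the setting. Of 28 intestine genes 12 bore a promoter peak (42.9%, interval 26.5 to 60.9; odds ratio 3.04, adjusted Fisher p = 0.0112), with the intestinal actin gene act-5 (signal 155), the fatty acid desaturase gene fat-6 (95.4) and the gut GATA factor gene elt-2 (94.3) the strongest, and cpr-5 and elt-4 without one. The gut call was lost with replicate 1 alone (9 of 28, adjusted Fisher p = 0.175) and held with replicate 2 alone (13 of 28), and among the 3356 strongest peaks only 1 of 28 remained, an odds ratio of 0.254 (adjusted p = 0.325). It was also lost against genes with a relaxed promoter peak (12 of 17, adjusted Fisher p = 0.214) and among peaks found in the strongest lists of both replicates (7 of 28, adjusted p = 0.226). The elt-2 peak was lost with replicate 2 alone and in the window of 250 bp either side, and both it and that of fat-6 lay outside the 3356 strongest. The other somatic lists did not pass. Because a gut promoter drives the fusion, this need not hold for LIN-35 in those tissues. A promoter peak was found at 1 of 20 muscle genes, the myosin chaperone gene unc-45 (968), at 2 of 27 neuron genes, of which ric-19 was the stronger (1740), and at 1 of 21 epidermis and cuticle genes, the GATA factor gene elt-3 (66.6), with adjusted Fisher p = 0.175, 0.175 and 0.132. Over the alternatives their odds ratios ran from 0 to 1.16, 0.232 to 0.549 and 0 to 0.301, and none passed. The elt-3 peak was found neither with replicate 2 alone nor among the 3356 strongest or those of both strongest lists, and unc-45 had none in the window of 250 bp either side. With replicate 2 alone 4 of 20 muscle genes bore a peak (odds ratio 1.16, adjusted Fisher p = 0.818). Chemoreceptor genes, most of which act in sensory neurons, were bound less often than other genes (13 of 1290, 1.01%, interval 0.590 to 1.72; odds ratio 0.0380, adjusted Fisher p = 1.59e-104). The 3 strongest of these peaks were at srh-16 (1620), srr-10 (1477) and sri-5 (1367), and sra-1 and sra-10 had none. The srr-10 peak was lost with replicate 2 alone, with assignment to the nearest start and in the window of 250 bp either side. The chemoreceptor odds ratio was 0.0573 with replicate 2 alone and 0.240 against genes with a relaxed promoter peak (13 of 63), still past the threshold.

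Most genes of the germline lists were unbound, but so were most protein-coding genes, of which 19.8% bore a promoter peak. The meiosis list and the P granule and germ line list did not differ detectably from other genes. Of 26 meiosis genes 3 bore a promoter peak (11.5%, interval 4.0 to 29; adjusted Fisher p = 0.487), with syp-3 the strongest (209), and the odds ratio of 0.527 turned to 1.40 in the window of 1000 bp upstream (8 of 26, adjusted p = 0.521) and to 0.185 with replicate 2 alone. The syp-3 peak had no partner in replicate 2, and was lost in the window of 250 bp either side and with assignment to the nearest start. Of 35 P granule and germ line genes 5 did (14.3%, 6.26 to 29.4; adjusted Fisher p = 0.527), with mes-2, a Polycomb group gene, the strongest (1986). None of the 31 major sperm protein genes, which include msp-10 and msp-113, had a promoter peak (interval up to 11%, adjusted Fisher p = 0.00455), and this call ended when each peak was given to the nearest start within 2 kb (3 of 31, adjusted p = 0.156). The small RNA pathway list had 14 of 36 genes (38.9%, 24.8 to 55.1; odds ratio 2.58, adjusted Fisher p = 0.0153), led by rde-4 (674), mut-15 (529) and mut-2 (430), with none at the Argonaute genes alg-2 and alg-3. That call was lost under 5 alternatives: with replicate 2 alone (10 of 36, adjusted Fisher p = 0.152), in the window of 250 bp either side (adjusted p = 0.150), with assignment to the nearest start (0.181), against genes with a relaxed promoter peak (0.625) and among peaks of both strongest lists (0.281). It held in the window of 1000 bp upstream (odds ratio 3.95). With assignment to the nearest start mut-15 and mut-2 lost their peaks and alg-2 gained one. Histone genes bore a peak in 8 of 72 cases (11.1%, 5.74 to 20.4; adjusted Fisher p = 0.105), with his-37 the strongest (759). The histone odds ratio of 0.505 passed the threshold with replicate 1 alone (6 of 72, adjusted Fisher p = 0.0176), with the window of 1000 bp upstream (adjusted p = 0.0127) and with assignment to the nearest start (adjusted p = 0.00501), and turned to 2.49 among genes with a relaxed pooled peak (8 of 11, adjusted p = 0.306). Histone and major sperm protein genes are near-identical copies, so reads may not have been placed uniquely and their counts are uncertain. Genes in a list are not independent replicates of the experiment, and neighbours can share a peak.

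**Figure D2:**
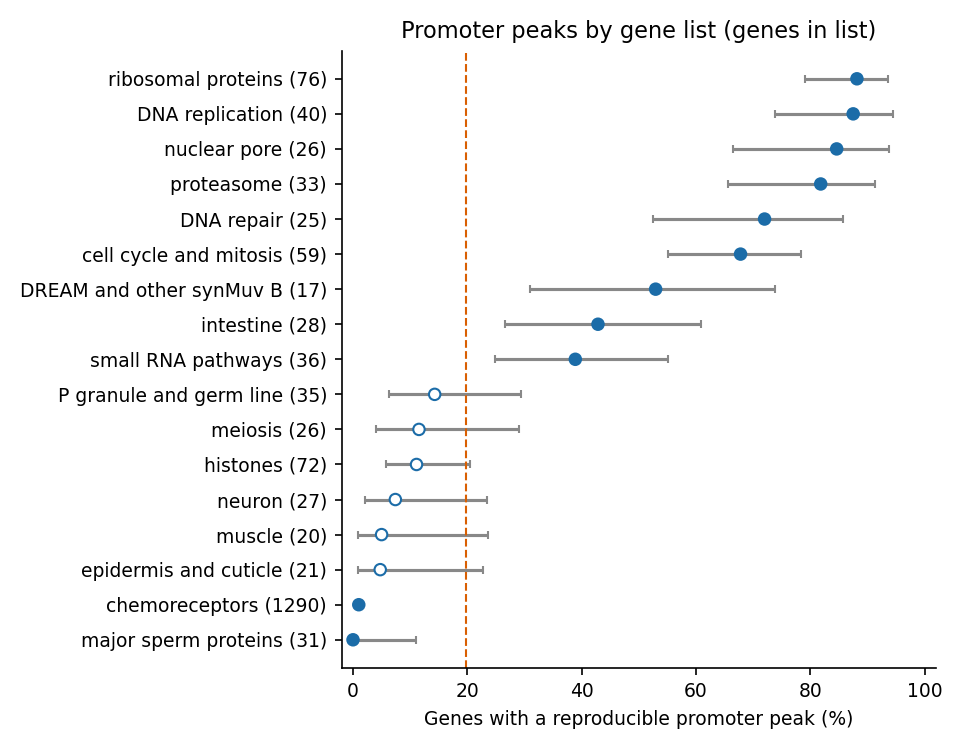
Percentage of the genes of each list with a reproducible promoter peak, with 95% Wilson intervals as bars, the number of genes in parentheses, filled points for lists past an adjusted p of 0.05 and a dashed line at the 19.8% of all protein-coding genes. Ribosomal protein, DNA replication, nuclear pore and proteasome genes lie above 80%, and chemoreceptor and major sperm protein genes lie near 0.

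Short non-coding genes also bore peaks. Highly transcribed short genes can attract signal without specific binding, and whether these peaks reflect specific binding was not tested. A promoter peak was found at 320 of 612 tRNA genes (52.3%, interval 48.3 to 56.2; odds ratio 8.21, adjusted Fisher p = 5.32e-128), at 115 of 346 snoRNA genes (33.2%, 28.5 to 38.4; odds ratio 3.60, adjusted p = 4.92e-24) and at 28 of 129 snRNA genes (21.7%, 15.5 to 29.6; odds ratio 1.98, adjusted p = 0.00459), where all other genes of any biotype are the background. Of that background 11.8%, 12.1% and 12.3% were bound, less than the 19.8% of protein-coding genes. The snRNA share was thus close to that of protein-coding genes. None of 20 rRNA genes (adjusted Fisher p = 0.203) and 29 of 194 lincRNA genes (14.9%, adjusted p = 0.272) were bound, and neither class passed. The snRNA call was lost among the 3356 strongest peaks (15 of 129, adjusted Fisher p = 0.160), and lincRNA genes passed with replicate 2 alone (33 of 194, odds ratio 1.60, adjusted p = 0.0214).

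Motifs for E2F, LIN-54 and GATA factors, of which the last regulate gut genes, were counted within 75 bp of each summit and in a window of the same width 500 bp away. The E2F consensus TTSSCGC was present at 12.7% of the summits (interval 11.9 to 13.5) and at 5.30% (4.79 to 5.87) of the flanking windows, a ratio of 2.39 (adjusted p = 1.21e-51, exact McNemar test with Benjamini-Hochberg adjustment over 7 motif tests). Its reversed spelling, a control for base composition, rose as well, from 2.38% to 7.75%, a ratio of 3.25. The ratio was thus higher for the control, whereas the difference in percentage points was higher for E2F, at 7.37 against 5.36, and among the 3356 strongest peaks at 12.3 against 8.05. These differences between E2F and its control were not tested. The LIN-54 or CHR consensus TTYGAA was less frequent at summits (34.6%, 33.5 to 35.8) than in the flanks (46.0%, 44.8 to 47.2; adjusted exact p = 2.52e-40), and its reversed control was lower by more, at 15% against 29.4%. The CHR difference was smaller among the 3356 strongest peaks (38.9% against 45%) and against the background peaks (37.3% in these). Both E2F and CHR were present in 6.38% of the summit windows and 2.26% of the flanks (adjusted exact p = 4.48e-33), a difference of 4.11 percentage points that was 2.58 with replicate 2 alone and 7.69 among the 3356 strongest peaks. The GATA consensus TGATAA was present at 23.3% of the summits (22.3 to 24.4) and 14.9% of the flanks (14 to 15.7; adjusted exact p = 9.75e-36), while its reversed control was at 9.86% and 11.1%. The GATA difference of 8.48 percentage points was 13.2 with replicate 2 alone. Among the 3356 strongest peaks the GATA difference turned round, with 13% at summits and 14.7% in flanks (adjusted exact p = 0.0545).

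The motifs at promoter summits differed between the gene lists. E2F sites lay at 24 of the 35 promoter summits of the DNA replication list (68.6%, interval 52 to 81.4), 21 of 40 of the cell cycle and mitosis list (52.5%, 37.5 to 67.1) and 10 of 22 of the nuclear pore list (45.5%, 26.9 to 65.3), against 412 of 2989 (13.8%, 12.6 to 15.1) at genes in no list. The adjusted p was 5.28e-12, 8.72e-08 and 0.00187, by Fisher's exact test over the lists. CHR sites lay at 71.4%, 80% and 81.8% of the summits of these lists, against 37.7% at genes in no list (adjusted Fisher p = 0.000285, 1.18e-06 and 0.000285). The DNA repair list also passed, with E2F sites at 7 of 17 summits (41.2%, adjusted Fisher p = 0.0214) and CHR sites at 15 (88.2%, adjusted p = 0.000213). CHR sites alone passed at 8 of 9 summits of DREAM and other synMuv B genes (88.9%, adjusted Fisher p = 0.00796) and 18 of 27 of proteasome genes (66.7%, adjusted p = 0.0113). The CHR control was not counted by list. The reversed E2F control was at 20%, 7.50%, 4.55% and 9.20% of the DNA replication, mitosis, nuclear pore and no-list summits. At DNA repair summits it was at 17.6% (3 of 17). Ribosomal protein summits carried an E2F site in 6 of 64 cases (9.38%, 4.37 to 19; adjusted Fisher p = 0.581), and the reversed control in 15.6%, and CHR sites in 32.8% (adjusted Fisher p = 0.686). Gut genes carried a GATA site at 10 of their 12 promoter summits (83.3%), against 596 of 2989 (19.9%) at genes in no list (adjusted Fisher p = 7.52e-05). Chemoreceptor genes also did, at 7 of 13 (53.8%, 29.1 to 76.8; adjusted Fisher p = 0.0226). No promoter summit of the DNA replication list had one. This comparison of lists was chosen after the peak lists had been examined. It was not matched for peak signal, with which motif shares changed. Among promoter summits, GATA sites lay at 6.21% in the 1678 strongest peaks and 39.6% in the 1678 weakest. Over all summits E2F sites fell from 24.1% to 7.63% and CHR sites from 48.6% to 31.2%. Median signal was 73.8 at bound gut genes and 611 at bound replication genes, against 131 in no list. How far signal accounts for the list differences was not tested.

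**Figure D3:**
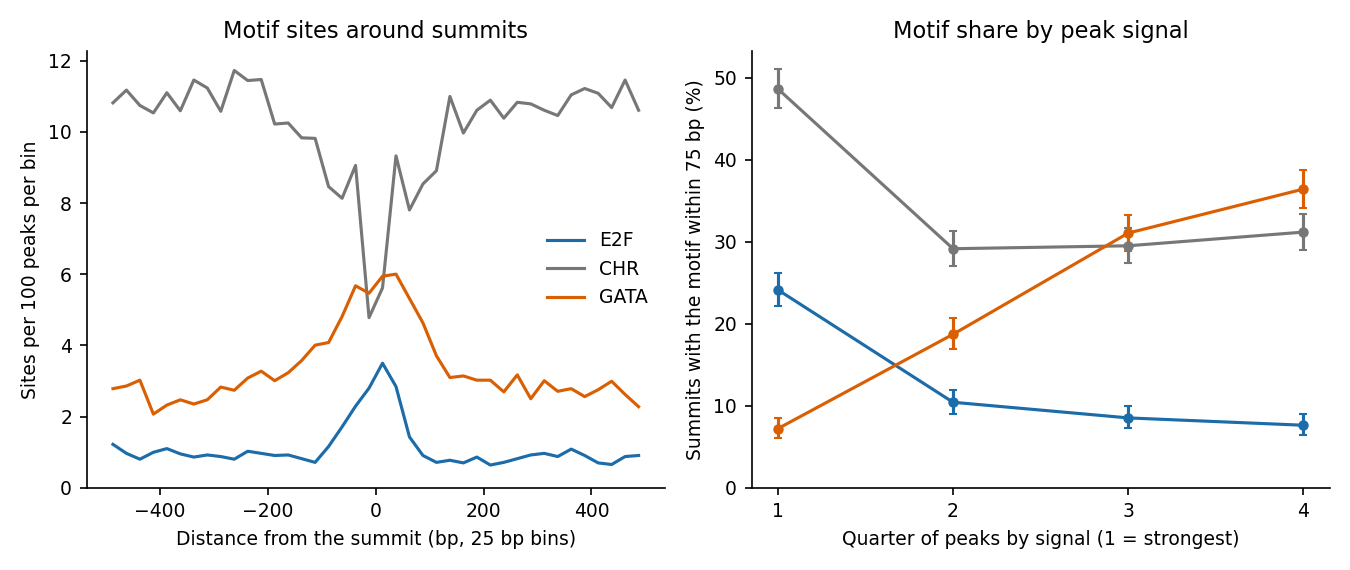
Left, sites of the E2F, CHR and GATA consensus per 100 reproducible peaks in bins of 25 bp against the distance from the summit in bp. Right, percentage of summits with each motif within 75 bp in 4 groups of 1678 peaks ordered by signal (1 the strongest), with 95% Wilson intervals; E2F falls from 24.1% to 7.63% and GATA rises from 7.21% to 36.4%.

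Genes on the X chromosome bore promoter peaks slightly less often than autosomal genes, with 476 of 2731 (17.4%, interval 16.1 to 18.9) against 3483 of 17242 (20.2%, 19.6 to 20.8; Fisher's exact test, two-sided, p = 0.000711). The difference was larger among the 3356 strongest peaks (8.79% against 13.3%, Fisher p = 7.17e-12). It was not detectable with replicate 2 alone (17.1% against 17.9%, p = 0.319), and per length the X chromosome held more peaks than the autosomes, 68.5 against 66.6 per Mb (exact binomial p = 0.388). Within autosomes, genes in the middle 50% of each chromosome were bound more often than those in the outer parts, with 2157 of 9596 (22.5%, 21.7 to 23.3) against 1326 of 7646 (17.3%, 16.5 to 18.2; Fisher p = 5.73e-17). In the window of 250 bp either side the shares were closer, 15.8% against 13.1% (Fisher p = 3.72e-07).

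At the genomic loci that gave parts to the transgene, peaks were found only at unc-119. Reads from the transgene copies may have been placed at the same coordinates. Peaks, or their absence, therefore cannot be assigned to the endogenous copies alone. In the gene lists, lin-35 (DREAM and other synMuv B) and ges-1 (intestine) counted as unbound. No reproducible peak, and no peak of the relaxed lists, overlapped ges-1 (chromosome V, 1427653 to 1432137) or lin-35 (chromosome I, 5807709 to 5815637) or their 2 kb upstream. In unc-119 (chromosome III, 10902641 to 10908935) there were 2 reproducible peaks. An intronic summit at 10905358 had signal 168 and ranked 2490 in the list of replicate 1 and 474 in that of replicate 2, and a summit at 10907777, in the promoter window of an internal transcript start, had signal 65.7 and ranked 7466 and 2847 in these lists. The latter was lost with replicate 1 alone, among the 3356 strongest peaks and among those of both strongest lists.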

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

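Across 36 tested or counted results, 208 of the 245 values under an alternative kept their direction and their side of the threshold or stayed in their interval. The set of 4695 peaks found in the strongest lists of both replicates was chosen after seeing the data. With 50% reciprocal overlap the shares of reproducible peaks found in replicate 1, replicate 2 and the strongest peaks of each were 97.4%, 78.1%, 93.8% and 61.9%. With summits within 100 bp they were 99.5%, 83.9%, 95.8% and 68.2%, and among the 3356 strongest peaks 99.9%, 97.5%, 99.9% and 89.2%. In the window of 1000 bp upstream to 200 bp downstream, the meiosis odds ratio rose to 1.40 and histones reached 0.393. In the window of 250 bp either side, 3 lists lost their call, DREAM and other synMuv B (2.52), small RNA (2.01) and ribosomal proteins (1.36). Their summits in the main window lay more than 250 bp upstream at 4 of 9, 5 of 14 and 53 of 67 bound genes. The median was 288 bp at ribosomal protein genes. Assignment to the nearest start ended the calls of small RNA (1.72) and major sperm proteins (0.367), and histones passed (0.311). Against genes with a relaxed pooled peak, DREAM and other synMuv B (1.40), small RNA (1.30) and intestine (2.24) lost their call and histones turned to 2.49, with 15, 24, 17 and 11 genes of these lists left and a bound share of the other genes near 51.8%, against 19.8% over all protein-coding genes. Among the strongest peaks intestine fell to 0.254, snRNA to 1.59 and lincRNA to 0.866, and the GATA difference to -1.70 percentage points. In the peaks of both strongest lists, small RNA (1.67) and intestine (1.95) lost their call. With either replicate alone the odds ratio ran from 1.78 to 2.58 for small RNA, 0.213 to 1.16 for muscle, 1.92 to 4.03 for intestine, 0.367 to 0.498 for histones and 1.20 to 1.60 for lincRNA, and the X difference from -2.90 to -0.800 percentage points. Per Mb the X chromosome held 1.85 more peaks. The reversed GATA control turned to 0.313 points in a window of 150 bp either side and 0.416 against pooled relaxed peaks. Apart from the summit positions given for the window of 250 bp either side, the causes were not tested. Of 518 values for 74 named genes, 45 gained or lost the promoter peak. The read depth is unknown, so how depth limits the weaker peaks cannot be stated.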

Other observations

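The comparisons of signal by list, of short words, of motifs by signal and of spacing were chosen after the peak lists had been examined. The same holds for the tests of ribosomal protein, proteasome and nuclear pore genes taken singly, for the odds ratio within groups of signal, for the count of intestine genes and the position of their summits, for the shares of list genes set against the replication list, and for GATA sites at non-coding starts. The design has 1 group, so no biological contrast was tested.

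Promoter peaks at cell cycle genes were among the strongest in the genome, and those at gut genes among the weaker. The median signal was 611 at the 35 bound DNA replication genes (interquartile range 383 to 880), 495 at 40 cell cycle and mitosis genes and 463 at 67 ribosomal protein genes, against 131 (76.0 to 295) at 3682 bound genes in no list. For each of these 3 lists the permutation p was 1e-05, the smallest that 100000 resamples can give (adjusted p = 5.33e-05 over 16 lists). The 9 bound DREAM and other synMuv B genes had a median of 752 (adjusted permutation p = 0.00115), nuclear pore genes 279 and proteasome genes 253 (adjusted p = 0.0091 for both). At the 12 bound intestine genes the median was 73.8 (54.7 to 88.2), lower than at genes in no list (adjusted permutation p = 0.0091). Summits at ribosomal protein genes lay a mean of 146 bp farther upstream of the annotated start than at DNA replication genes (two-sided permutation p = 2e-05, the smallest that 100000 resamples can give here, where the p of the smaller tail was doubled).

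Among the 2080 words of 6 bases, ranked by the z score of their count near summits against that in the flanks, ACGCAG came first, at 17.7% of the summit windows and 3.22% of the flanks. GAGAGA followed, at 30.2% against 8.15%, and ACGCGC ranked 5, at 12.6% against 2.09%. Of the words that hold GATA, GATAAG ranked 32, at 16.2% against 6.12%, and TGATAA ranked 115, at 23.3% against 14.7%. By the ratio of the shares GCGCGC came first, at 7.55% against 1.02% (7.40 times), ACGCAG ranked 4 (5.49 times) and GAGAGA 21 (3.71 times). Which proteins bind these words was not tested.

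The endogenous ges-1 and lin-35 loci held no peak even in the relaxed lists. At the density of the 30000 pooled peaks, 1.94 would fall in the 6485 bp of ges-1 and its 2 kb upstream and 2.97 in the 9929 bp of lin-35, while unc-119 held 6 pooled peaks in 8295 bp against 2.48 at that density.

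E2F and CHR sites were most frequent at the strongest peaks and GATA sites at the weakest. Of the 1678 strongest peaks 24.1% had an E2F and 7.21% a GATA site, and of the 1678 weakest 7.63% and 36.4% (Fisher's exact test, two-sided, p = 2.09e-40 and 1.65e-99), while CHR sites were at 48.6% and 31.2% (Fisher p = 5.43e-25). The reversed E2F control fell likewise, from 12.9% to 3.93%, while the reversed GATA control was at 8.22% and 9.95%. One hypothesis is that the reproducible set mixes separate sites, some with E2F and some with GATA motifs. Within the 4 groups of 1678 peaks ordered by signal, a GATA site was rarer at summits with an E2F site, with a pooled odds ratio of 0.545 (interval 0.436 to 0.683, Cochran-Mantel-Haenszel p = 6.66e-08, n = 6712 peaks). Both were found at 99 summits, where 153 would have been if the motifs were independent within these groups. This test may also reflect base composition, since the motifs differ in it.

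CHR and E2F sites kept certain spacings. With the CHR on the 5' side of the E2F site, 45 windows had 1 bp between the sites, 44 had 9 bp and 41 had 0 bp, whereas the other 59 arrangements up to 30 bp had at most 16 windows and a median of 4. The 9 bp spacing was present in 5.17% of the 851 reproducible windows with an E2F site and in 1.58% of 1643 such background windows (p = 1.07e-06, Fisher's exact test, adjusted p = 6.64e-05 over 62 arrangements). A composite element of both sites with 9 bp between them may therefore mark part of the set. The spacings of 0 and 1 bp were at 4.82% and 5.29% against 3.35% and 4.14%, and their differences from the background did not pass (adjusted Fisher p = 0.407 and 0.616).

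Ribosomal protein, proteasome and nuclear pore promoters were bound about as often as those of DNA replication genes in the main window (88.2%, 81.8% and 84.6% against 87.5%), but less evenly with assignment to the nearest start (56.6%, 63.6% and 65.4% against 77.5%; Fisher p = 0.0276, 0.207 and 0.397) and in the window of 250 bp either side (18.4%, 57.6% and 61.5% against 80%; Fisher p = 1.11e-10, 0.0445 and 0.156). Together they carried an E2F site at 20.4% of 113 summits, against 13.8% at genes in no list (Fisher p = 0.0534) and 68.6% in the DNA replication list (p = 4.11e-07), but the lists differed, so each was read by itself. At ribosomal protein genes the share was 9.38%, far below the replication list (Fisher p = 1.59e-09). It did not differ detectably from genes in no list (Fisher p = 0.363). So low a share argues against recruitment through this E2F consensus at most of these summits. No other E2F spelling was tested, so recruitment through other sites stays open. Signal at any open or highly transcribed promoter also stays an open explanation. At nuclear pore genes the share was 45.5%, above genes in no list (Fisher p = 0.000351), the outcome set as counting against open promoters alone. However, only promoters with a peak were searched, and genes whose promoters hold E2F sites would give this share under either explanation. The test therefore cannot decide, and a LIN-35 complex recruited through E2F sites remains possible. At proteasome genes the share of 25.9% (7 of 27) was below the replication list (Fisher p = 0.00185) and not detectably above genes in no list (Fisher p = 0.0874), and the reversed control was at 22.2%, which leaves both open. CHR sites lay at 66.7% of these summits against 37.7% at genes in no list (adjusted Fisher p = 0.0113). Their reversed control was not counted by list, so this cannot decide whether a DREAM complex binds there. It does not bear on E2F motifs either.

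Summits outside promoter windows made up 3318 of the 6712 reproducible peaks, and 827 of them (24.9%) lay in the window of a non-coding gene. This count depends on the window. The share inside was 60.8% with 1000 bp upstream to 200 bp downstream and 38.1% with 250 bp either side. Weak peaks near the threshold are a possible explanation, but 40.5% of the 3356 strongest summits (interval 38.8 to 42.2) also lay outside. The values fixed beforehand were below 25% for this explanation and at least 40% with its whole interval against it, and the interval reaches below 40%. Distal elements bound by gut GATA factors are another: a GATA site lay at 27.4% of the outside and 19.4% of the inside summits (Fisher p = 5.92e-15), with 18.6% at the non-coding starts and 30.3% at the 2491 summits at no annotated start. Lower signal outside promoters could explain this GATA difference. Within the 4 groups ordered by signal the pooled odds ratio was 1.18 (interval 1.05 to 1.33, Cochran-Mantel-Haenszel p = 0.00533, n = 6712 peaks). From the strongest, groups 1, 2 and 3 had more GATA sites outside than inside. The shares were 9.79% against 6.21%, 22.7% against 14.2% and 33.0% against 28.7% (Fisher p = 0.0152, 8.01e-06 and 0.0637). Among the 1678 weakest peaks the order turned, with 34.5% outside and 39.6% inside (Fisher p = 0.0365). Whether the GATA difference follows signal cannot be decided, because the groups of signal go different ways. That difference also bears on only part of the outside summits, since 27.4% of them carried a GATA site. Weak peaks stay undecided as well, because the interval of 38.8 to 42.2 spans the 40% fixed beforehand.

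The intestine list passed with replicate 2 alone and not with replicate 1 alone. The difference itself was not detectable, with 7 genes (asp-1, elt-7, ftn-1, ifc-2, mtl-1, mtl-2 and pho-1) bound with replicate 2 only and 3 (elt-2, ifb-2 and pgp-1) with replicate 1 only (exact McNemar p = 0.344), so chance at a list of this size stays open. Among the strongest peaks found in replicate 2 only, 17.3% of the summits lay in exons against 4.28% in replicate 1 only (Fisher p = 1.8e-42). This was the direction set beforehand for background from RNA-rich gene bodies in replicate 2. RNA was not measured, and the pooled background peaks also lay in coding exons (23.9%) and UTR exons (4.19%). The test therefore cannot tell RNA-rich gene bodies from other background. At the gut genes themselves, 10 of the 13 promoter summits of replicate 2 (76.9%, interval 49.7 to 91.8) lay upstream of the start, too few to decide. GATA sites were also more frequent in replicate 2 only, at 38.9% against 20.8% (Fisher p = 3.71e-36), so more signal at GATA sites in that replicate remains open too.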
